A study of Homo sapiens with 8 samples.

How the data were processed

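Total RNA from 4 human breast cancer cell lines was measured on 8 Agilent 1-colour whole-genome expression arrays. Each line gave 1 array of cells transfected with a mimic of the microRNA miR-1285-5p and 1 array of cells transfected with a negative control mimic, and RNA was taken 2 days after transfection, per the labels' protocols. The series' design text speaks of 2 experiments per line, and whether an array holds RNA of both is not stated. All 8 arrays shared 1 slide and 1 scan, so neither could be set against the groups.

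The scanner files hold the spot intensity on a linear scale as deposited, made with Agilent Feature Extraction 11.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, the processed signal had its background subtracted and its spatial trend removed within each array, and signals near background were replaced by small surrogate values. No scaling between arrays had been applied to these signals. A second table holds log2 values that the authors deposited for the same arrays. Set against the scanner files, each of its columns equalled the log2 processed signal plus 1 constant per array for the probes with 1 spot, with a largest deviation of 2e-06. Of the 300 probes with 10 spots, 14 to 23 per array, the dim CDH1 probe in MDA-MB-231 among them, lay over 0.01 and up to 0.27 from it. The Pearson r across probes was 1.0, and the SD of the difference over probes well above background 0.0002 to 0.0006. The constants lay between -6.74 and -6.23 and the column medians between -3.94 and -3.75. Scale, centring and direction of that table were thereby known, and the tool that made it is not given in the sources used here.

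Each array had 62976 spots, of which 60901 were not controls. Control spots and 57 to 97 spots per array with an outlier flag were left out, spots of 1 probe were averaged, and 58188 probes had a value on all arrays. Between 46.4% and 49.9% of the probes of an array were well above background by the scanner software's flag, and no spot was saturated. The 75th percentile of the processed signal lay between 75.5 and 107, the median coefficient of variation of replicate spots between 3.61% and 3.76%, and the slope of the spike-in controls between 0.999 and 1.04. For arrays the number of arrays limits the precision, and here it was 1 per condition and line.

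Gene names came from the files and were updated through a RefSeq gene table of assembly GRCh38, used for names only. Of the probes, 31099 were named through their accession, 3365 through a current symbol and 496 through an older symbol, while 23228 kept the name in the files. The probes carried 43395 distinct names, 21546 of them gene symbols. Probe coordinates are those of the files, on build hg19. Exon and UTR positions on that build were not used here.

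The main values were log2 of the processed signal minus the 75th percentile of each array. A gene was represented by the probe with the highest mean over the 8 arrays. Genes were tested where that probe was well above background on at least 4 of the 8 arrays, which left 22076 genes. Of the 5078 genes with more than 1 probe at that level, 1694 had a probe whose mean change had the other sign. The test was limma's moderated test (lmFit and eBayes, two-sided, limma 3.58.1 in R 4.3.3) with the cell line as a block, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Error values are limma's standard errors over the 4 lines. The labels name the cell line of each array, so the 2 arrays of a line form a pair. As a check of the pairing, the deviations of the 2 arrays of a line from their group means had correlations of 0.946 to 0.968, and the highest correlation with an array of another line was -0.101. The 4 lines are the replicates of the mimic's effect, and nothing in the files gives the spread between cultures of 1 line. With 4 pairs an exact two-sided sign-flip test cannot give a p below 0.125.

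Within a line there was no replicate and no test. Differences between the 2 arrays were taken over genes well above background on at least 1 of them, and genes at least 2-fold higher or lower were counted. The similarity of the lines was the Pearson correlation across genes of the log2 changes for the 6 pairs of lines.

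Of 18 gene lists fixed before the data were examined, 15 were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 15 lists. Camera with an estimated correlation and fry were alternatives. The lists were DNA replication and G1/S, mitosis and G2/M, p53 targets, interferon response, NF-kB and inflammatory cytokines, unfolded protein and ATF4 response, cholesterol synthesis, estrogen response, epithelial, mesenchymal, TGF-beta and SMAD targets, nuclear envelope, microRNA pathway, apoptosis regulators and ribosomal proteins. The candidate targets had 3 members, under the minimum of 5 for a list test. Markers of stromal, endothelial and immune cells and of the cell lines' identity were read as levels. Within a line, the median change of a list was placed among 10000 random lists of the same size matched on signal level, which describes those 2 arrays and is not a test of the condition.

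Genes named in the text were chosen by a rule set before the data were examined. It names NEMP1, SMAD4 and CDH1 always. It names the 10 genes with the largest decrease and the 10 with the largest increase among those past the threshold with 1 direction in all 4 lines, filled up to 10 with the genes of the smallest unadjusted p and 1 direction where fewer passed. Within each line it takes the 3 largest differences of each sign among genes well above background on both arrays, and in each list up to 4 members with the smallest p. Probes without a gene symbol were counted and not named.

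The fit and the list test were tested on simulated data. With 200 of 22076 simulated genes changed, 64% of the genes changed 2-fold and 96% of those changed 4-fold passed the threshold, with 7 false calls, and 4.94% of the unchanged genes had an unadjusted p below 0.05. Each simulated change was the same in all 4 lines, and the genes varied independently. These shares therefore do not carry over to genes whose change differs between lines. The check of the list test does not carry over to lists of correlated genes. Alternatives fixed beforehand were normexp background correction with an offset of 50, quantile normalization, a 75th percentile over probes detected on all arrays, the authors' deposited values, the mean of the probes of a gene, no filter and a filter on all 8 arrays, each line left out in turn, no block, and eBayes with trend and robust fitting. A search for the seed site of miR-1285-5p in 3' UTRs was planned and not run, because no transcript sequences were used here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.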

Results

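The series measured the transcript levels of 4 established human breast cancer cell lines after transfection with a synthetic mimic of miR-1285-5p or with a negative control mimic. A mimic is a short double-stranded RNA that enters the silencing machinery in the place of a natural microRNA. MDA-MB-231, HCC1954, MCF-7 and HCC1937 each contributed 1 mimic array and 1 control array, 8 arrays in all. MCF-7 is an estrogen receptor positive line, HCC1954 carries an amplified ERBB2 gene, and MDA-MB-231 and HCC1937 are lines of the triple-negative class. The changes below are log2 levels on the mimic array minus those on the control array of the same line, averaged over the 4 lines with limma's standard error where no line is named.

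The first question was whether NEMP1, formerly TMEM194A, was lower after the mimic, since this gene of an inner nuclear membrane protein was the target followed up in the study. NEMP1 was lower on the mimic array of each line, to 26.7% of the control level in MDA-MB-231, 32.9% in HCC1954, 42.3% in MCF-7 and 93.2% in HCC1937. The mean log2 change was -1.21 ± 0.30 (limma's moderated SE, n = 4 lines), from a control level of 2.12 above the 75th percentile of the array. The SD of the 4 changes was 0.79, so the spread between the lines is wider than that error shows. SMAD4, the shared transducer of TGF-beta signalling, differed by 0.14 ± 0.10 and was higher in 3 of the 4 lines, with a change of the other sign at its second probe and a mean of 0.07 without MDA-MB-231. CDH1, which encodes E-cadherin, differed by 0.33 ± 0.11 and was higher in all 4 lines, though its probe was not well above background on either MDA-MB-231 array. None of the 3 genes passed the threshold over all genes. The adjusted p from limma was 0.294 for NEMP1, 0.327 for CDH1 and 0.561 for SMAD4. The exact sign-flip test gave p = 0.125 for NEMP1, the smallest value that 4 pairs allow, beside an unadjusted p of 0.00727 from limma. Adjusted over the list alone, NEMP1 (0.0218) and CDH1 (0.0387) passed. For NEMP1 this is not independent evidence, because the study may have chosen it on these arrays. The pass of CDH1 depends on NEMP1 being a member of the list and ranking ahead of it, so it is not independent of that choice. Neither passed there without MDA-MB-231 (0.0671 for both), without HCC1954 (0.0878 and 0.128) or without MCF-7 (0.0711 and 0.107), and CDH1 did not after normexp background correction (0.0791), with the authors' values (0.0628), without the filter on dim probes (0.0611) or without the block (0.927). NEMP1 was read by 1 probe, at chromosome 12, 57450036 to 57450095 on hg19.

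Over the 4 lines the decreases with the smallest unadjusted p included those of TRAPPC6B, a subunit of a vesicle tethering complex, with a log2 change of -1.61 ± 0.16, and FZD3, a receptor for Wnt proteins, with -1.40 ± 0.20. BCL7B, a subunit of SWI/SNF chromatin remodelling complexes, differed by -1.08 ± 0.17, COMMD8 by -0.98 ± 0.13, and RUVBL1, an ATPase of several chromatin complexes, by -0.89 ± 0.09. In the other direction, GLYCTK, which encodes glycerate kinase, differed by 1.15 ± 0.09, the calcium channel subunit gene CACNG1 by 1.02 ± 0.13, and the ubiquitin ligase gene RCHY1 by 0.997 ± 0.14. None of these values passed the threshold. By the rule that chose them, each of these genes had 1 direction in all 4 lines. The size of several rests on dim signals: after normexp background correction, whose offset shrinks dim differences, TRAPPC6B was at -0.22, FZD3 at -0.51, GLYCTK at 0.28 and CACNG1 at 0.18, whereas BCL7B was at -0.97 and COMMD8 at -0.93.

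The other genes of this selection were also values that did not pass. TCP10L3 (-0.84 ± 0.11), LARP4B-DT (-0.82 ± 0.13), FBXL17 (-0.76 ± 0.10), the Rho family gene RND1 (-0.67 ± 0.08) and LRRC70 (-0.56 ± 0.09) were lower on the mimic arrays. HMCN1 (0.93 ± 0.12), CYRIB (0.90 ± 0.13), a gene of a protein that binds the GTPase Rac1, the endocytic adaptor gene DAB2 (0.89 ± 0.12), TRAPPC2 (0.77 ± 0.10), the homeobox gene MSX2 (0.75 ± 0.11), the junctophilin gene JPH1 (0.70 ± 0.10) and CTNNAL1 (0.63 ± 0.09) were higher. Several of them were dim. TRAPPC6B was well above background on all 4 control arrays and on 1 mimic array, LARP4B-DT on 3 control arrays and 1 mimic array, HMCN1 on 1 control array and 3 mimic arrays, and CACNG1, DAB2 and RND1 on 2 control arrays and 2 mimic arrays, while RUVBL1, FBXL17, COMMD8, BCL7B, TRAPPC2, RCHY1, CTNNAL1, CYRIB and JPH1 were well above background on all 8 arrays. Of the 20 genes of this selection 14 had a change smaller by over 1.5 times after normexp. With the mean of the probes of a gene 4 did, GLYCTK at 0.71, LARP4B-DT at -0.49, TRAPPC2 at 0.07 and FBXL17, which had 3 probes and 1 of them with a change of the other sign, at -0.20. The RUVBL1 probe lies at chromosome 3, 127819456 to 127819515, the BCL7B probe at chromosome 7, 72950766 to 72950825, the FZD3 probe at chromosome 8, 28421786 to 28421845, and the GLYCTK probe at chromosome 3, 52329208 to 52329267, all on hg19.

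**Figure D1:**
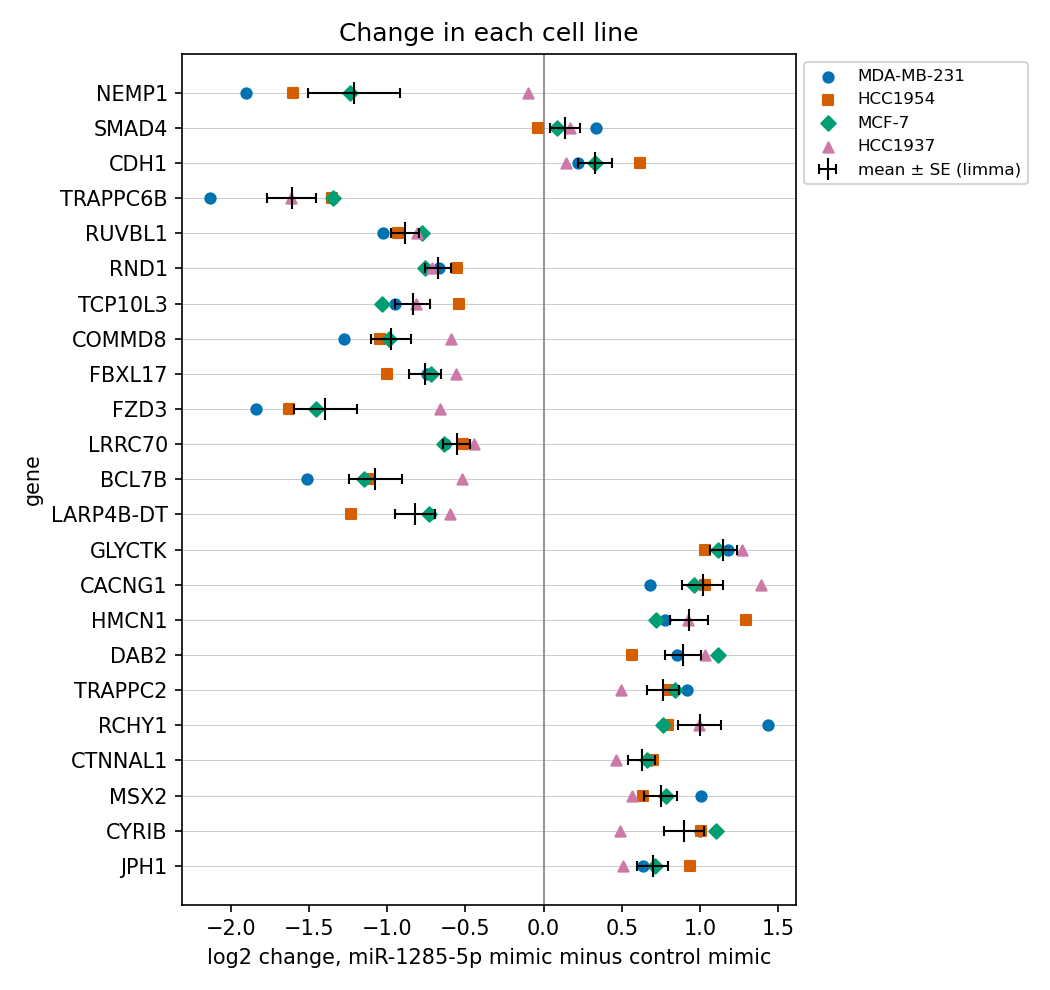
Log2 change of each named gene, mimic minus control array, in the 4 cell lines (coloured symbols, 1 pair of arrays each), with the mean and limma's standard error over the lines in black. NEMP1 lies between -1.90 and -1.24 in MDA-MB-231, HCC1954 and MCF-7 and at -0.10 in HCC1937, whereas RUVBL1 lies between -1.03 and -0.78 in all 4 lines. RUVBL1 was chosen for its 1 direction and small p, which favours a small spread over the lines.

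Of the 22076 genes tested, 0 passed an adjusted p of 0.05 with limma, and the smallest adjusted p was 0.294. At an unadjusted p below 0.05 there were 2921 genes, 1499 higher and 1422 lower, where 1104 would be expected by chance. In all 4 lines 5211 genes had 1 direction, 2575 higher and 2636 lower. This is 23.6% of the genes, against 12.5% if the signs of the lines were independent. The genes at an unadjusted p below 0.05 numbered 1853 without MDA-MB-231, 1841 without HCC1954, 2010 without MCF-7 and 3414 without HCC1937, and 80 without the cell line as a block.

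Among the fixed gene lists, genes of DNA replication and the G1/S transition were lower as a group, with 21 of 24 members lower and a mean log2 change of -0.19. Their examples were CCNE2, which encodes cyclin E2, at -0.75 ± 0.24, RRM2, a subunit of ribonucleotide reductase, at -0.39 ± 0.12, the replication licensing gene CDC6 at -0.32 ± 0.10 and the helicase subunit gene MCM7 at -0.31 ± 0.10. CDC6 was at -0.15 after normexp, and RRM2 at -0.24 with the mean of its probes. Camera gave the list an adjusted p of 0.000141 with the preset correlation, and an adjusted p of 0.829 with an estimated correlation. The list's median change was -0.17 in MDA-MB-231, -0.21 in HCC1954, -0.38 in MCF-7 and 0.04 in HCC1937. No member passed over all genes or adjusted over the list alone.

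Interferon response genes were lower as a group, with 19 of 24 members lower and a mean log2 change of -0.19. USP18, which removes the ubiquitin-like ISG15 from proteins, differed by -0.64 ± 0.17, IFI44L by -0.60 ± 0.21 and the oligoadenylate synthetase gene OAS3 by -0.40 ± 0.09. IRF7, a transcription factor of interferon induction, went the other way at 0.59 ± 0.21. The adjusted p was 0.00803 with the preset correlation and 0.829 with an estimated correlation, and without HCC1954 it was 0.260, with a mean of -0.06 for the list and -0.36 for IFI44L. After normexp USP18 was at -0.34, OAS3 at -0.21 and IRF7 at 0.31. Ribosomal protein genes were slightly lower, with 20 of 23 members lower and a mean of -0.09. RPS3 differed by -0.26 ± 0.09 and RPL3 by -0.24 ± 0.09. For this list the adjusted p was 0.0228 with the preset correlation, 0.829 with an estimated correlation and 0.174 after quantile normalization. Leaving out MDA-MB-231 or HCC1954 gave adjusted p values of 0.202 and 0.0992, with means of -0.05 and -0.08, and in HCC1937 13 of the 23 members were higher. Of the random lists matched on signal level, 7.83% had a median as low in MDA-MB-231, 5.04% in HCC1954 and 31.09% in MCF-7. In HCC1937 the median was 0.02. The lower values were therefore not extreme for genes of that signal level, and a response particular to ribosomal genes was not shown.

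Genes of the unfolded protein and ATF4 response were higher as a group, with 15 of 20 members higher and a mean log2 change of 0.18. SEL1L, a component of the machinery that removes misfolded proteins from the endoplasmic reticulum, differed by 0.74 ± 0.15, the protein disulfide isomerase gene PDIA4 by 0.55 ± 0.14, HERPUD1 by 0.41 ± 0.13 and TRIB3 by 0.24 ± 0.09. The adjusted p was 0.0293 with the preset correlation and 0.829 with an estimated correlation. It was 0.260 without HCC1954, with a mean of 0.08 for the list and 0.27 for HERPUD1, and 0.108 without HCC1937. The list's median was 0.43 in HCC1954, 0.14 in MCF-7 and 0.14 in HCC1937, but -0.07 in MDA-MB-231, where 12 of 20 members were lower. Over the 4 lines no list passed with an estimated correlation or with fry, where the smallest adjusted p was 0.619. Without MDA-MB-231 the microRNA pathway list passed fry as higher, with 0.0460.

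The other 11 lists did not pass camera. In the NF-kB and cytokine list 14 of 18 members were lower, with a mean of -0.21 and an adjusted p of 0.105. Without MDA-MB-231 the mean was 0.08 (adjusted p 0.863), and the list passed as lower without HCC1954 (0.00373) or MCF-7 (0.0178). Its members TNF (-0.94 ± 0.45), IL1B (-0.63 ± 0.26), BIRC3 (-0.54 ± 0.28) and SOD2 (-0.33 ± 0.14) had their lowest values in MDA-MB-231, except BIRC3 in MCF-7. Without MDA-MB-231 TNF was at -0.35, IL1B at -0.33 and SOD2 at -0.16, and without MCF-7 BIRC3 was at -0.24. Of the estrogen response genes 11 of 14 were higher, with a mean of 0.14 and an adjusted p of 0.188, or 9 of 14 with a mean of 0.06 and an adjusted p of 0.854 without MCF-7. The exception CA12, a carbonic anhydrase gene, differed by -1.40 ± 0.28 and passed adjusted over the list alone (0.0401), though it was well above background on 4 of the 8 arrays. It did not pass there in 6 of 12 alternatives: after normexp (0.216), where its change was -0.45, without the filter on dim probes (0.0872), without the block (0.999), and without MDA-MB-231 (0.0988), MCF-7 (0.105) or HCC1937 (0.107). Mitosis and G2/M genes were mixed (11 higher, 13 lower, adjusted p 0.847, and higher with a mean of 0.07 without MDA-MB-231), with CDC25C at -0.35 ± 0.11 and MKI67 at 0.15 ± 0.08.

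Among p53 targets 12 of 21 were higher (adjusted p 0.785), with a mean of 0.06 that was -0.03 without HCC1954. The cell cycle inhibitor gene CDKN1A differed by 0.86 ± 0.25, with 1.82 in HCC1954, and was at 0.54 without that line and at 0.51 after normexp. ZMAT3 differed by 0.34 ± 0.09, or 0.14 after normexp, while the death receptor gene TNFRSF10B differed by -0.53 ± 0.13. Cholesterol synthesis genes went both ways (9 of 20 higher, adjusted p 0.847), with CYP51A1, which encodes lanosterol demethylase, at -1.11 ± 0.24, INSIG1 at -0.54 ± 0.19 and HMGCR at 0.27 ± 0.10. Nuclear envelope genes did so too (11 of 19 higher, adjusted p 0.729). There BANF1 differed by 1.01 ± 0.25 and SUN2 by 0.53 ± 0.14, or 0.24 after normexp, and the lamin B receptor gene LBR by -0.77 ± 0.20. Of the microRNA pathway genes 8 of 15 were higher (adjusted p 0.832), with TNRC6A at 0.53 ± 0.13, DICER1 at 0.31 ± 0.08 and TNRC6B at -0.31 ± 0.09. Apoptosis regulators were evenly divided (10 of 20 higher, adjusted p 0.785), with the survival gene MCL1 at 0.72 ± 0.20 and BCL2 and BMF at -0.54 ± 0.19 and -0.52 ± 0.15. BCL2 was at -0.16 after normexp. Epithelial genes (10 of 16 higher, adjusted p 0.606), mesenchymal genes (9 of 13 higher, 0.213, but 0.0261 without MCF-7) and TGF-beta and SMAD targets (10 of 15 higher, 0.406) did not pass over the 4 lines either. SMAD6, an inhibitor of that pathway, differed by -0.51 ± 0.15 and CCN2 by 0.33 ± 0.13. No member of these 11 lists passed over all genes.

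**Figure D2:**
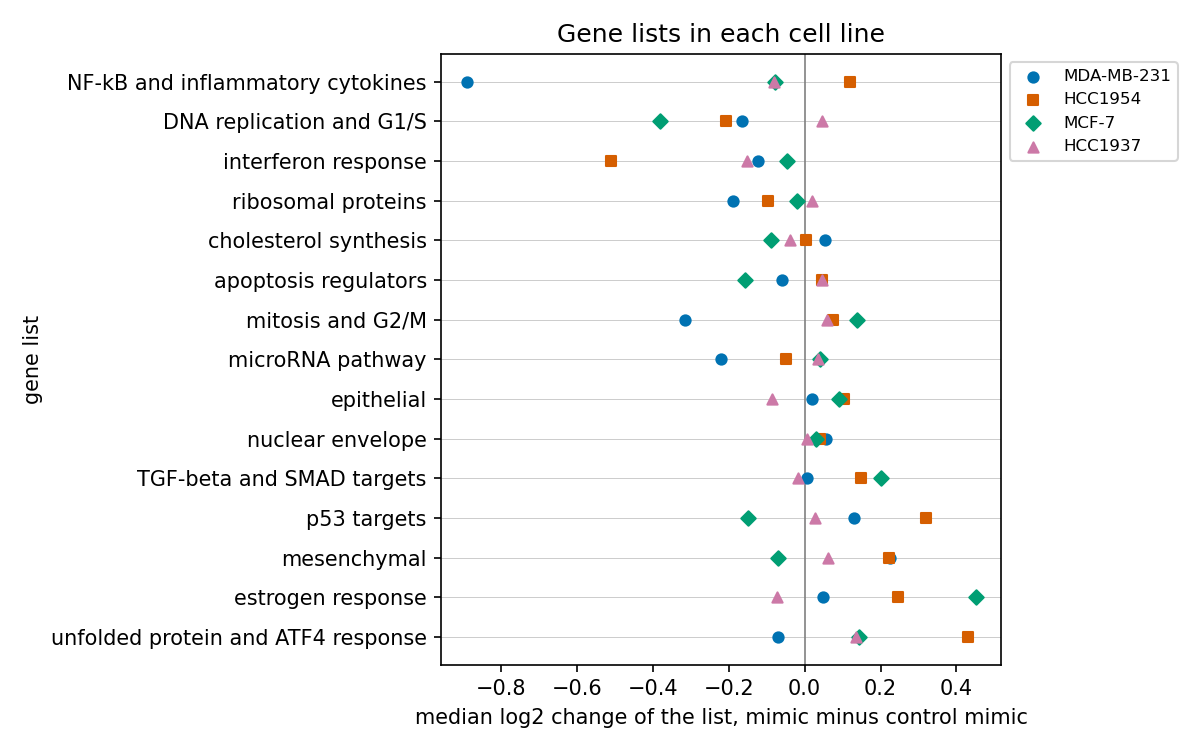
Median log2 change of each of the 15 tested gene lists, mimic minus control array, in each cell line (1 pair of arrays per symbol). The NF-kB list lies at -0.89 in MDA-MB-231 and between -0.08 and 0.12 in the other lines, and the interferon list lies at -0.51 in HCC1954.

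Within MDA-MB-231 the largest decreases included those of 2 cytokine genes. CCL20 was 5.45-fold and CSF3, which encodes granulocyte colony-stimulating factor, 5.25-fold lower on the mimic array, and LEPROTL1 was 4.80-fold lower. USP44 was 4.89-fold, the amino acid transporter gene SLC36A1 4.79-fold and the retinol carrier gene RBP4 4.53-fold higher. All 18 measured NF-kB and cytokine genes were lower in this line, with a median of -0.89, and 0% of 10000 random lists had a median as low. Of the mitosis genes 22 of 24 were lower there, with a median of -0.31 that 0.05% of random lists reached, while in the other 3 lines 17 or 18 of the 24 were higher. Counting all genes well above background on at least 1 array, 701 were at least 2-fold higher and 803 lower. These are differences between 2 arrays, without replicates, in this line and in the others below. With detection on both arrays required, the total of 1504 became 554, and after normexp background correction it was 188. The log2 differences of the named genes after normexp were 0.48 for USP44, 0.49 for RBP4 and -1.14 for CCL20, against -2.11 for CSF3 and 1.89 for SLC36A1, and LEPROTL1 was at -1.12 with the mean of its probes.

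In HCC1954 the gene TMEM225B was 9.96-fold lower, PPP1R1B 5.87-fold and the secreted breast protein gene PIP 5.76-fold lower, whereas SLC36A1 was 7.42-fold, the methionine sulfoxide reductase gene MSRB3 6.91-fold and the cornified envelope gene SPRR1B 6.12-fold higher. Interferon response genes had a median of -0.51, with 21 of 24 lower, and unfolded protein response genes a median of 0.43, with 16 of 20 higher. The p53 targets had a median of 0.32, with 13 of 21 higher. For these 3 lists 0% of 10000 random lists were as extreme in the same direction. There were 908 genes at least 2-fold higher and 682 lower. Their total of 1590 became 678 with detection on both arrays and 185 after normexp. After normexp the log2 difference was 0.90 for MSRB3, 1.33 for SPRR1B, -1.40 for PPP1R1B and -1.56 for TMEM225B. TMEM225B also depended on the choice of probe, since the mean of its probes gave -1.27 in place of -3.32.

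In MCF-7 the nucleotidyltransferase gene TENT5C was 5.26-fold, the selenoprotein gene SELENOP 3.75-fold and SGO1-AS1 3.39-fold lower, and KRT32 was 4.02-fold, GGT5 3.85-fold and MICAL1 3.74-fold higher. Of the estrogen response genes 12 of 14 were higher in this line, with a median of 0.45, and 22 of 24 DNA replication genes were lower, with a median of -0.38. In both cases 0% of 10000 random lists were as extreme. Mitosis genes went the other way from MDA-MB-231, and p53 targets the other way from HCC1954. Of the mitosis genes 18 of 24 were higher, with a median of 0.14 that 0.35% of random lists reached, and of the p53 targets 15 of 21 were lower, with a median of -0.15 that 0.55% reached. The differences between lines were not tested, for lack of replicates within a line. At least 2-fold differences were found for 606 genes higher and 509 lower, a total of 1115 that became 314 with detection on both arrays and 70 after normexp. There the log2 difference was 0.43 for MICAL1, 0.48 for GGT5, 0.96 for KRT32, -0.38 for SGO1-AS1 and -1.16 for SELENOP.

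HCC1937 had 556 genes at least 2-fold higher and 399 lower, 955 in total, 105 with detection on both arrays and 46 after normexp. Interferon response genes had a median of -0.15 in this line, with 17 of 24 lower, that 0.05% of random lists reached. Unfolded protein response genes had a median of 0.14, with 16 of 20 higher, that 0.04% reached. KRTAP23-1 was 10.4-fold, GMDS-DT 5.09-fold and NRROS 4.88-fold higher, and ANO9 was 7.32-fold, MIA2 3.18-fold and TRAPPC6B 3.07-fold lower. The first gene of each direction had no difference of that size and sign in the other 3 lines, where KRTAP23-1 lay between -0.22 and 0.87 and ANO9 between -0.09 and 1.28. After normexp the log2 difference was 1.69 for KRTAP23-1, 1.22 for GMDS-DT, 0.61 for NRROS, -0.96 for ANO9 and -0.48 for TRAPPC6B. With the mean of their probes MIA2 was at -0.10 in place of -1.67, and GMDS-DT at 0.31 in place of 2.35. The SD of the log2 differences over genes detected on both arrays was 0.25 in HCC1937, against 0.41 in MDA-MB-231, 0.41 in HCC1954 and 0.34 in MCF-7. Over genes well above background on at least 1 array it was 0.57 in HCC1937, against 0.71 in MDA-MB-231, 0.67 in HCC1954 and 0.55 in MCF-7.

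The last comparison asked how alike the lines responded. SLC36A1 was higher in all 4 lines, by 2.26 in MDA-MB-231, 2.89 in HCC1954, 1.65 in MCF-7 and 0.71 in HCC1937. TENT5C was lower by -1.38 and -1.83 in MDA-MB-231 and HCC1954 and by -2.40 in MCF-7, and lay at -0.02 in HCC1937. LEPROTL1 went from -2.26 in MDA-MB-231 through -1.47 and -1.07 in HCC1954 and MCF-7 to -0.11 in HCC1937. Across the 22076 genes, which are not independent replicates, the log2 changes of MDA-MB-231 had a Pearson r of 0.273 with those of HCC1954 and 0.278 with those of MCF-7, and HCC1954 and MCF-7 had 0.210. The same correlations with HCC1937 were 0.125 for HCC1954, 0.0643 for MDA-MB-231 and 0.0461 for MCF-7. Between 51.9% and 61.6% of genes had the same sign in a pair of lines, where chance gives 50%. No array is shared between lines. The mean r of the 6 pairs was 0.166, and it became 0.271 over genes well above background on all 8 arrays and 0.314 after normexp background correction.

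Markers of cell line identity differed between the lines. On the control arrays the log2 level of ESR1, the estrogen receptor gene, was 2.76 in MCF-7, -0.20 in HCC1937 and -2.10 in HCC1954. ERBB2 was 9.07 in HCC1954 against 4.67 in MCF-7. VIM, the vimentin gene, was 9.23 in MDA-MB-231 and 0.56 in MCF-7, and the basal keratin gene KRT5 was 3.66 in HCC1954 and 2.41 in HCC1937 and not well above background in the others. Of 14 measured markers of stromal, endothelial and immune cells, 6 were well above background on all 8 arrays and 2, COL3A1 and MS4A1, on none. The leukocyte gene PTPRC differed between mimic and control by -0.09 in MDA-MB-231, 0.05 in HCC1954, 0.10 in MCF-7 and 0.06 in HCC1937. Larger differences were seen for DCN, the decorin gene, at 4.39 in HCC1954, where only the mimic array was well above background, for ACTA2, the smooth muscle actin gene, at 1.53 in HCC1954, for CD14, at 1.11 in MDA-MB-231 and -0.66 in HCC1954, and for the T cell gene CD3D, at -0.71 in HCC1937. Others of that size were LUM at 0.67 in MDA-MB-231, PECAM1 at -0.62 in HCC1954 and CD19 at -1.31 in HCC1937, where 1 array was well above background. VWF was at 2.38 in MDA-MB-231, where neither array was well above background. Over the 4 lines 0 of the 9 tested markers of this kind passed adjusted over the list alone.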

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

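The tests of the chance splits and of the HCC1937 pattern, apart from that of the signal scale, were chosen after the results were seen. Of 109 sets of 4 values, 5 had 1 line far from the others, and chance alone gives about 1 in 20. The log2 change of CYRIB was 0.49 in HCC1937 against 0.997 to 1.1 in the other lines. HERPUD1 differed by 0.84 in HCC1954 against 0.22 to 0.32. CA12 differed by -2.51 in HCC1954 against -1.13 to -0.97. CLDN4 differed by 0.35 in HCC1954 against 0.09 to 0.12. RPLP0 differed by -0.24 in MDA-MB-231 against -0.08 to -0.07.

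The direction of 2 named genes was opposite in 2 lines by at least 2-fold, each line with an array well above background, which was not tested for lack of replicates within a line. ANO9, at -2.87 in HCC1937 and 1.28 in MDA-MB-231, is left out because neither MDA-MB-231 array was well above background. RBP4 was at 2.18 in MDA-MB-231 and at -1.13 in HCC1954. PPP1R1B was at 1.89 in HCC1937, where 1 of its 2 arrays was well above background, and at -2.55 in HCC1954. After normexp neither was 2-fold opposite, with RBP4 at 0.49 and -0.76 and PPP1R1B at 0.24 and -1.40 in those lines.

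HCC1937 differed from the other lines in the size of its change, with NEMP1 at -0.10 and 105 genes at least 2-fold apart among those detected on both arrays. For a compressed signal scale on its arrays, the planned ratio was the SD over genes of its control array against the other controls, 0.854 times that of the other lines. That ratio also depends on how far the lines differ, so it cannot isolate the scale. The slope of the spike-in controls, not part of the plan, was 1.02 on its mimic array and 1.04 on its control array. On the other arrays it was 0.999 to 1.02, which argues against compression. The SD of mimic minus control over genes detected on both arrays, 0.25, was smaller in HCC1937 than in each other line. Over genes detected on at least 1 array it was 0.57, against 0.55 in MCF-7. Interchanged arrays are argued against too. Over 243 genes that went 1 way in the other 3 lines with a mean of at least 2-fold, the median in HCC1937 was 0.17 ± 0.04 (SE over genes) in their direction. A weaker action of both oligonucleotides in this line may account for the pattern and stays open, as does an untested difference in biology between the lines. For genes higher in the other lines the median in HCC1937 was 0.557 times the smallest of the others. For genes lower it was 0.926 times, because MDA-MB-231 also had a low median there (-0.17 against -0.16). Each line's value is over its own set of genes, chosen on the other 3 lines. The means of the lower genes lay further apart than these medians, at -0.48 ± 0.16 (SE over genes) in MDA-MB-231 and -0.10 ± 0.04 in HCC1937.

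For the count of 0 genes past the threshold the splits of the 8 arrays into 4 and 4 decide nothing, since a count cannot be lower: 32 of 32 reach 0 by construction, and the highest other count was 0. At an unadjusted p below 0.05 the real split gave 2921 genes, and 3 of the 32 splits, the real one included, gave as many. The highest other value, 3394, came from 2 splits that part only the pairs of MDA-MB-231 and HCC1954, the lines with the most 2-fold differences. Both keep the mimic and control labels of these lines and so carry part of the real contrast. The share of 3 in 32 therefore cannot tell how often chance gives as many genes. With 1 of these 2 lines turned, the count was 970. Among the 8 splits that part all 4 pairs the highest other count was 1909, with HCC1937 turned. Those 8 are too few for a share under 0.05, so chance is not excluded. In them, 1 split, the real one, gave as many as 5211 genes of 1 direction in all lines, and the highest other had 3836. For the lists, 14 of the 32 splits gave at least the 4 lists of the real split, and the highest other gave 7, so chance is not excluded for the preset-correlation calls.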

How the results depend on the processing

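No gene passed the threshold under any of the 13 alternatives to the limma fit, with smallest adjusted p values between 0.103 with trend and robust fitting and 1.0 without the replicate block. Beside that count of 0, the genes at an unadjusted p below 0.05 numbered 2921 in the main setting, 80 without the block, 1853 without MDA-MB-231, 1841 without HCC1954, 2010 without MCF-7 and 3414 without HCC1937. NEMP1 was lower under all of these, between -1.58 and -0.98, with adjusted p values of 0.124 to 1.0, the fit without the pairing giving -1.21. Of 1029 values of single genes over the lines, 1027 kept their direction, which says nothing about their size. Much of this count was fixed by construction, so it does not measure robustness. The fits without the filter, with the filter on all arrays, without the block and with trend and robust fitting leave a gene's mean change as it is. Leaving out a line cannot turn a gene that had the same direction in every line. After normexp 34 of 82 named genes had a change smaller by over 1.5 times, with TRAPPC6B at -0.22, TCP10L3 at -0.11, HMCN1 at 0.12 and LARP4B-DT at -0.07, and with the mean of the probes 9 did. The mean of the probes of a gene turned SMAD4 to -0.039 and CLDN4 to -0.15, since it includes probes left out of the main values. Within lines, 97 of 120 values of named genes moved by less than the spread of the line's differences and 23 moved by more without turning. Quantile normalization, the other 75th percentile and the authors' values changed the counts of 2-fold genes by less than 1.5 times. The other 75th percentile and, apart from a few probes with several spots, the authors' values differ from the main values by 1 constant per array. Only the centring of an array could therefore move the counts there. After normexp, whose offset shrinks dim differences by construction, the counts of 2-fold genes were 188 in MDA-MB-231, 185 in HCC1954, 70 in MCF-7 and 46 in HCC1937. With detection on both arrays, which removes genes, they were 554, 678, 314 and 105. The mean r between lines was 0.314 and 0.271 under these 2 settings.

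Of 15 lists 4 passed in the main setting, 1 without the block, 2 to 6 with a line left out, and, over all 4 lines, 0 with an estimated correlation or with fry. Without MDA-MB-231 the microRNA pathway list passed fry (0.0460). Adjusted over the list alone, NEMP1 missed the threshold in 3 of 13 alternatives, CDH1 in 7 of 12 and CA12 in 6 of 12. With an estimated correlation the adjusted p of the DNA replication, interferon, unfolded protein and ribosomal lists was 0.829 and with fry 0.619. Without the replicate block the DNA replication list passed, and the adjusted p values of the interferon, unfolded protein and ribosomal lists were 0.724, 0.0838 and 0.322. Quantile normalization gave the ribosomal list 0.174. The NF-kB list passed with normexp (0.0305) and without the filter (0.0489). Leaving out a line gave adjusted p values of 3.03e-06 to 0.0164 for DNA replication, 0.000406 to 0.260 for interferon, 0.00122 to 0.260 for the unfolded protein list, 0.0171 to 0.202 for ribosomal genes, 0.00373 to 0.863 for NF-kB with its direction turned without MDA-MB-231, 0.0261 to 0.564 for mesenchymal genes with a pass without MCF-7, 0.0629 to 0.735 for mitosis, 0.269 to 0.863 for p53 targets and 0.443 to 0.938 for cholesterol synthesis, the last 3 with a turned direction in 1 case each. Directions also turned, far from the threshold, with normexp for mitosis (0.999) and cholesterol synthesis (0.887) and with the filter on all 8 arrays for apoptosis regulators (0.982). The cause was not tested except where the setting's construction gives it. Slide and scan could not be blocked, being 1 each, the 3' UTR seed alternatives were not run, and 24 of the named genes, dim on at least 1 array, have no value under the filter on all 8 arrays. Between 46.4% and 49.9% of the probes of an array were well above background, and differences at the others rest on signals near background or on surrogate values.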

Other observations

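The tests of seed action, of the control oligonucleotide and of signal level and GC content for GACGTA were chosen after the results were seen. The other tests in the next paragraphs were set before their values were known. MRPL44 and MRPS9, genes of mitochondrial ribosomal proteins, the proteasome subunit gene PSMD2, the phosphatase gene PPM1B and GLOD4 were lower in all 4 lines, with mean log2 changes of -1.48, -0.63, -1.03, -0.90 and -0.89. None passed the threshold, and all were chosen after their values were seen, as genes whose probe holds the word GTGAGAT. This word is the site complementary to positions 2 to 8 of miR-1285-5p, whose sequence was taken from general knowledge and not from the labels. Over all 66 genes whose probe holds it the mean log2 change was -0.19 ± 0.04 (SE over genes, which are not replicates), with -0.21 in MDA-MB-231, -0.23 in HCC1954, -0.29 in MCF-7 and -0.04 in HCC1937. The median of the 66 mean changes was smaller, at -0.11. The NEMP1 probe does not hold the word.

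The lower values of these genes rank GTGAGAT 1 from the lowest of 13429 words of 7 bases, and its reverse complement ATCTCAC, with a mean of -0.0041, ranks 5498. That rank is for the mean over the lines. By line GTGAGAT ranked 9 in MDA-MB-231, 5 in HCC1954, 1 in MCF-7 and 2436 in HCC1937. The signal level and GC content of the probes are argued against, since 0% of 10000 random gene sets matched on both had a mean as low. Weaker binding at the word itself, for instance to leftover mimic, stays open: other probes of 17 of the genes, which lack the word, had a mean of -0.15 ± 0.09, too uncertain to tell. In the same 17 genes the probes with the word had -0.24 ± 0.09, a mean difference of -0.09 ± 0.06. Action of the mimic through its seed would give such a rank of 1 and remains a hypothesis. The word follows from the sequence of the microRNA and was not picked by its rank, but this test was chosen after the results were seen. A probe covers 60 bases of a transcript, so genes without the word are not genes without a site.

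The 43 genes whose probe holds GACGTA, a word picked as the highest of 4086 of 6 bases so that its rank is no evidence in itself, had a mean of 0.25 ± 0.06, with 0.28 in MDA-MB-231, 0.38 in HCC1954, 0.21 in MCF-7 and 0.13 in HCC1937. Examples chosen after their values were seen were TNFRSF11B, the osteoprotegerin gene, at 1.34, BANF1 at 1.01 and CHD5 at 0.95, none past the threshold. To allow for the choice of the word, the changes were shuffled among genes of the same signal level and GC content and the highest word was taken anew. In 0% of 1000 shuffles was its z, the mean change times the square root of the number of genes over the SD of all genes, as high, with a highest of 5.22 against 6.37 for GACGTA, which argues against signal level and GC content. Other probes of 7 of the genes had a mean of 0.10 ± 0.07, which leaves an effect of binding at the word open. In the same 7 genes the probes with the word had 0.27 ± 0.14. A candidate explanation is that the word matches the seed of the control oligonucleotide, whose action would lower such genes on the control arrays. The reverse complement TACGTC ranked 869 from the highest, as that explanation allows, but the sequence of the control is not given in the sources used here, so the explanation stays open.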
